A study of Danio rerio with 48 samples.

How the data were processed

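PolyA RNA from 48 pools of 15 zebrafish heads, 6 pools for each of 4 concentrations (DMSO vehicle, 0.88, 1.57 and 2.8 µM PFOS) at each of 2 ages, was sequenced as single reads of 75 cycles after 13 cycles of PCR from 500 ng of RNA, per the labels' protocols. Libraries were randomised before preparation and sequenced in 3 pools of 16, per the labels' protocols, and the sequencing pool of each library is not given in the sources used here.

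Per the submitters' processing notes, STAR 2.5.3a, Partek 8.0.19.0428 and the GRCz11 assembly were used; the gene annotation is not given in the sources used here. The deposited raw table holds expected counts per gene (25377 genes), in which 81.2% of values are whole within 0.01 and the rest are fractions. The deposited normalized table holds log2 values after quantile normalization for 20466 genes, per the file headers and the range of its values, with a lowest value of -13.29. Coordinates and gene names are those in the deposited tables. No column was left unassigned to a sample, no pair of libraries was identical, and the highest correlation between libraries was 0.988.

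Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, which kept 20021 genes holding 99.93 to 99.97% of each library's counts, and library sizes were scaled by TMM. All 48 libraries were fitted in 1 model with 8 groups and no covariate, by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each concentration was compared with DMSO of the same age, and 2.8 with 0.88 µM; a trend per µM, the difference between ages of the 2.8 µM effect and age in DMSO were tested in the same fit. Sharing the spread over all 8 groups gives steadier estimates and assumes that the groups vary alike. Log2 CPM values used a prior count of 2. A standard error was computed as the absolute log2 fold change over the square root of F.

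The design, the gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The 63 lists held 2043 members as written, of which 1956 (95.7%) matched a gene of the table and 1815 were tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Genes named for a comparison passed its threshold, had a gene name and not an identifier only, and had a mean log2 CPM of at least 1, and were those with the highest absolute log2 fold change: 8 higher and 8 lower at 2.8 µM, 4 and 4 for lower doses, trends, the difference between ages and 2.8 against 0.88 µM, and 6 and 6 for age, fewer where fewer passed. Up to 4 called members with the smallest p were taken from each list that passed or held at least 3 called genes. A gene outside the rule is named where it passed over its list alone, had the lowest p or made up a count of 5 or fewer. Adjustment over a list alone does not account for the 63 lists, so about 5% of lists would hold a passing member by chance.

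A list's level in a library is the mean log2 CPM of its tested members. These levels were compared by exact permutation tests over all 924 splits of 6 against 6, adjusted over 30 tests, and correlations used 100000 permutations of deviations from group means. The fit was tested on simulated counts and on thinned real counts with 200 changed genes among 20021; in simulated counts it recovered 16.4, 65.7 and 86.4% of genes changed 1.5-fold, 2-fold and 4-fold with 4 false calls, and in thinned counts it made 1 false call. Intervals and standard errors follow the spread between pools, and reads were counted without molecular identifiers.

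The settings fixed in advance were RLE normalization, no filter, a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate letter as a block, limma-trend on the quantile normalized values, leaving out each library in turn, and for the agreement between ages a mean log2 CPM of at least 3. Chosen after seeing the data were a fit without the 3 libraries with a median correlation under 0.95 with the others of their age, 3 surrogate variables (sva 3.50.0) and limma with sample quality weights. No library was left out of the values reported as main. Genes removed by the filter were not tested, and reads were not analysed here.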

Results

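Head transcriptomes of zebrafish larvae were measured after exposure to perfluorooctane sulfonic acid (PFOS), a persistent fluorinated surfactant, to ask which molecular events accompany the effects of such compounds on larval behaviour in a light and dark assay. Each of the 48 libraries held polyA RNA from a pool of 15 heads taken in front of the swim bladder. Embryos of a mixed wild-type line were kept in 0.88, 1.57 or 2.8 µM PFOS, or in the vehicle alone (0.4% dimethyl sulfoxide, DMSO), with daily renewal. Heads were collected at 4 or 5 days post fertilisation (dpf), with 6 pools in each of the 8 groups. The deposited counts summed to between 14475198 and 28926584 per library, and 20021 genes were tested. The labels do not say which pools came from separate clutches, so p-values measure the spread between these pools.

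Age separated the libraries more than PFOS did. The first principal component of log2 CPM (library-scaled counts) held 30.8% of the variance and parted most 4 dpf from 5 dpf pools, and the second held 17.3%. In 3 libraries the median correlation with the other libraries of the same age was low, at 0.922 for 2.8 µM replicate A at 4 dpf, 0.941 for 1.57 µM replicate D at 5 dpf and 0.915 for 0.88 µM replicate H at 5 dpf. Every other library was at 0.959 or above. The median standard error of a log2 fold change between 2 groups was 0.25. When known changes were put into thinned real counts of 20021 genes for 2.8 µM against DMSO at 4 dpf, the test recovered 16.4% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 90.9% of those changed 4-fold.

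**Figure D1:**
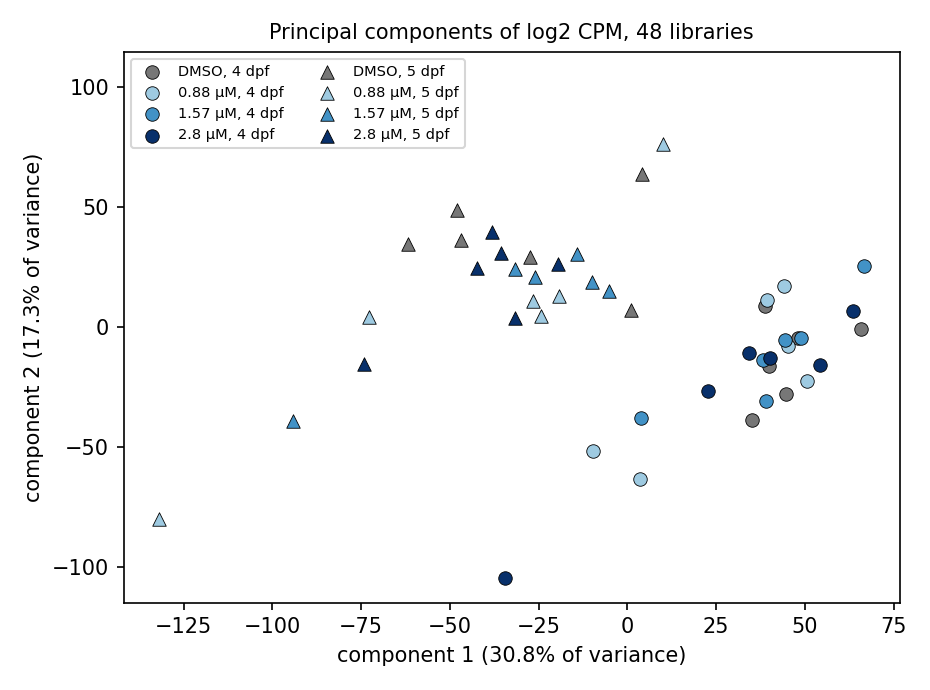
Principal components of log2 CPM for the 48 libraries, with component 1 (30.8% of variance) on the x axis and component 2 (17.3%) on the y axis. Each point is 1 pool, circles are 4 dpf, triangles are 5 dpf and darker blue is a higher PFOS concentration; the lowest circle, at -34.4 and -104.8, is 2.8 µM replicate A.

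In heads at 4 dpf, genes of neuronal signalling lay lower at 2.8 µM PFOS than in DMSO, by small amounts. Voltage-gated sodium and potassium channel genes had a median log2 fold change of -0.41, with 36 of 41 members lower. Genes of GABA signalling, the main inhibitory transmitter system, had a median of -0.38 with 29 of 34 lower, and glutamate signalling genes had -0.26 with 37 of 41 lower. Synaptic vesicle genes had a median of -0.2 with 27 of 35 lower, and circadian clock genes had -0.18 with 32 of 36 lower. On the higher side, all 68 cytosolic ribosomal protein genes lay above DMSO with a median of 0.67, all 36 nuclear genes of oxidative phosphorylation had 0.47, lens crystallins had 0.51 and epidermis and keratin genes had 0.24. Markers of some non-neural tissues also lay higher: fibroblast and matrix genes had a median of 0.19 (44 of 49 higher), cartilage 0.23 (34 of 37), bone 0.3 (19 of 24), skeletal muscle 0.22 (51 of 60) and endothelium 0.16 (25 of 34). Markers of some other tissues did not: hepatocytes had -0.15, pancreas -0.6, intestine 0.02 and ionocytes -0.07, and none of these 4 lists passed camera (adjusted p = 0.844, 0.824, 0.968 and 0.165).

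These differences between groups of genes passed a competitive test but not stricter ones. By camera, which compares a list with all other genes and presets the correlation between its members at 0.01, 29 of the 63 fixed lists passed, 19 higher and 10 lower. The adjusted p was 1.76e-10 for the channel list, 1.58e-09 for GABA, 9.82e-09 for glutamate, 0.000463 for synaptic vesicles, 8.03e-05 for the clock, 1.76e-10 for ribosomal proteins, 2.9e-06 for oxidative phosphorylation, 0.00186 for lens, 2.51e-06 for epidermis, 0.00124 for fibroblasts, 0.000802 for cartilage, 0.00263 for bone, 0.000491 for muscle and 0.00701 for endothelium. Other splits of these pools into groups passed a median of 16 lists by this same test, so these adjusted p are too small to be taken as they stand. With an estimated correlation 0 lists passed. The adjusted p was 0.461 with an estimated correlation for the channel, GABA, glutamate, clock, epidermis, bone and endothelium lists, 0.524 for cartilage, 0.548 for synaptic vesicles and oxidative phosphorylation, 0.553 for ribosomal proteins and 0.56 for lens, fibroblasts and muscle. By fry, which asks whether a list's genes move 1 way on balance without comparing it with other genes, 0 lists passed. In none of these lists did a member pass, adjusted over the list alone or over all genes.

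Some of the higher lists moved with the low-correlation pool of that group, 2.8 µM replicate A. Its mean ribosomal protein level of 9.75 log2 CPM was the highest of its group, which averaged 8.01 ± 0.95 (SD, n = 6) against 7.6 ± 0.46 (SD, n = 6) in DMSO (exact permutation p = 0.409, two-sided). Within groups at 4 dpf the ribosomal protein level followed the library scaling factor, which is computed from the same counts, with Pearson's r = -0.93 and Spearman's rho = -0.85 over 24 libraries (permutation p = 1e-05, the smallest 100000 permutations can give, and 3e-05; adjusted 2.8e-05 and 7e-05 over 7 relations). Without the 2 farthest libraries r was -0.89. At 5 dpf r was -0.95 and rho -0.96 (permutation p = 1e-05 and adjusted 2.8e-05 for both), and r was -0.92 without the 2 farthest. Without the 3 low-correlation libraries, an alternative chosen after seeing the data, the medians were 0.09 for ribosomal proteins, 0.11 for oxidative phosphorylation and 0.04 for lens crystallins, and these 3 lists no longer passed camera (adjusted p = 0.265, 0.0634 and 0.895). Muscle went to 0.14 and the clock to -0.1 (0.0131 and 0.0164), while epidermis stayed at 0.24, fibroblasts were at 0.27, cartilage at 0.21, bone at 0.27 and endothelium at 0.16. The neuronal medians were -0.33 for channels, -0.34 for GABA, -0.3 for glutamate and -0.24 for synaptic vesicles. The glutamate level was lower in the pools with a low neuron marker level: at 2.8 µM it was 3.77 to 3.92 log2 CPM in replicates D, E and H, whose neuron levels were low, and 4.29 to 4.48 in A, G and I. In DMSO it was 4.18 and 3.83 in replicates D and I, also low, and 4.46 to 4.67 in the others. The replicate letters of these groups differ: 2.8 µM held E (3.77) and no F, and DMSO held F (4.56) and no E. Letter and concentration are thus partly confounded in this comparison. The neuron marker list had a median log2 fold change of -0.18 (camera adjusted p = 0.0133; 0.56 with an estimated correlation) and of -0.23 without the 3 libraries (7.05e-05). Its level averaged 6.23 ± 0.27 log2 CPM (SD, n = 6) at 2.8 µM and 6.38 ± 0.27 (SD, n = 6) in DMSO (exact permutation p = 0.284, two-sided, adjusted p = 0.749 over 30 such tests).

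**Figure D2:**
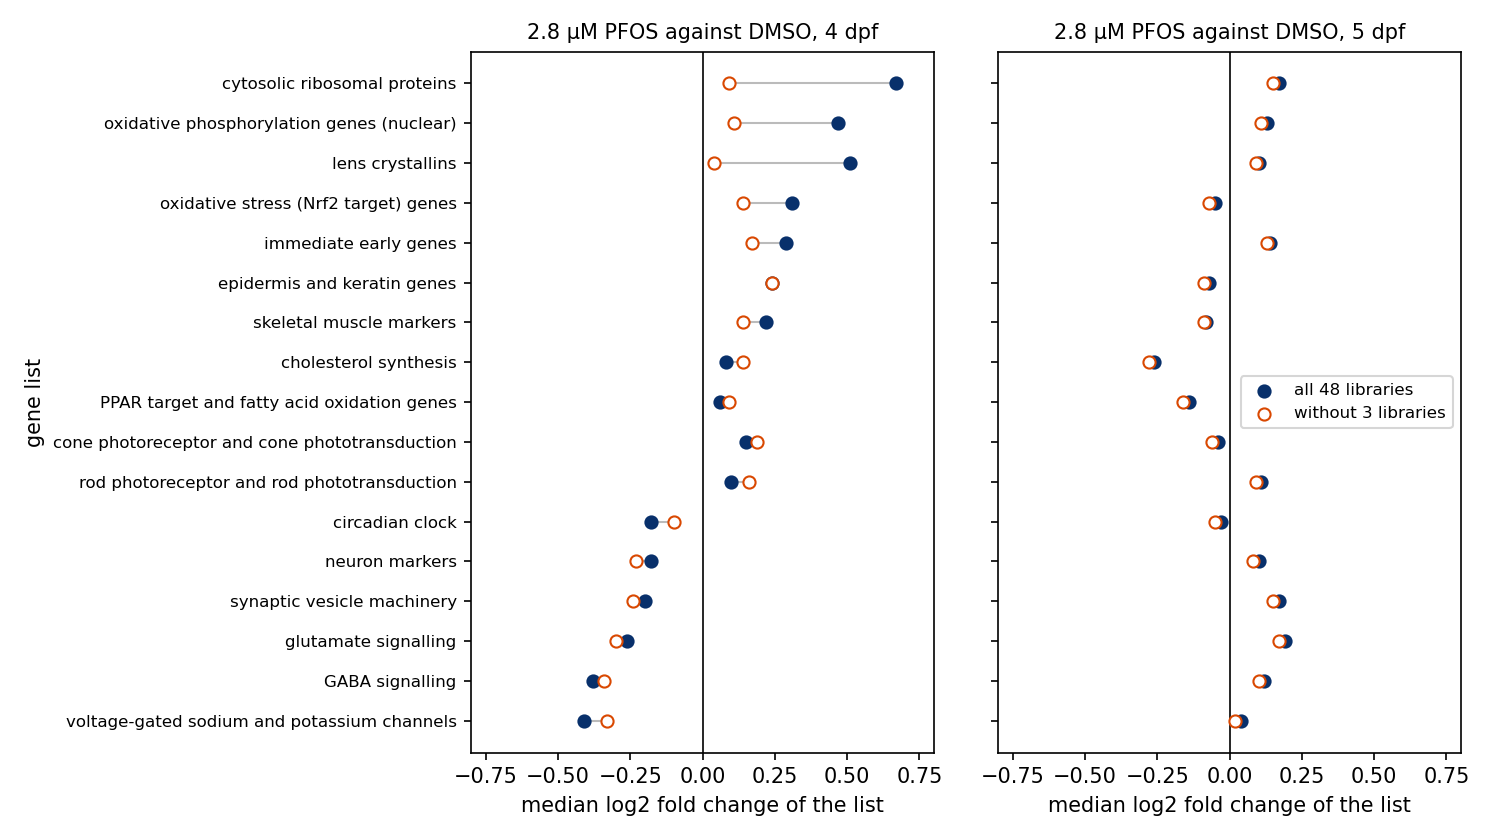
Median log2 fold change (x axis) of 17 gene lists (y axis) for 2.8 µM PFOS against DMSO at 4 dpf (left) and 5 dpf (right), with all 48 libraries (filled) and without 3 low-correlation libraries (open). The ribosomal protein median at 4 dpf moves from 0.67 to 0.09, and the GABA signalling median from -0.38 to -0.34.

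At 2.8 µM and 4 dpf 1202 genes had an unadjusted p under 0.05 by edgeR's quasi-likelihood test. Of 100 splits of these pools into groups, the real one included, 27 had as many, so that number is not beyond chance. No single gene passed by this test (lowest adjusted p = 0.748). The count was also 0 by DESeq2, by limma-trend on the deposited quantile normalized values and with 3 surrogate variables, and 248 (40 higher, 208 lower) by limma with sample quality weights. Adjusted over the list alone, ccng1 (cyclin G1, a p53 target; chromosome 14, 22129096 to 22140214, GRCz11) passed with a log2 fold change of 0.78 ± 0.24 (SE; edgeR adjusted p = 0.0375 over the list, 0.748 over all genes). So did irbpl, of the pineal list (chromosome 12, 2660733 to 2663472), at -0.83 ± 0.24 (SE; edgeR adjusted p = 0.0185 over the list, 0.748 over all genes). Of the 63 lists, 2 held such a member, and about 5% would by chance, so these 2 genes are not beyond chance. Targets of PPAR, the nuclear receptors of fatty acid oxidation, had a median of 0.06 and rod and cone phototransduction genes had medians of 0.1 and 0.15, and none of these 3 lists passed camera. Without the 3 low-correlation libraries the rod list, at 0.16, and the cone list, at 0.19, did (camera adjusted p = 0.0159 and 8.95e-05 at the preset correlation, the only one run on that fit). In the full fit they had an adjusted p of 0.56 and 0.677 with an estimated correlation. For 74.4% of genes the 95% interval of the fold change excluded both a doubling and a halving.

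In heads at 5 dpf, genes with a name and a mean log2 CPM of at least 1 were ranked by p at 2.8 µM. The first was six7, a transcription factor of cone photoreceptors (chromosome 7, 7401692 to 7420302, GRCz11). Its level was 5.25 ± 0.2 log2 CPM in DMSO, 5.34 ± 0.22 at 0.88 µM, 5.54 ± 0.17 at 1.57 µM and 5.87 ± 0.22 at 2.8 µM (SD, n = 6 each). The log2 fold change of six7 at 2.8 µM was 0.62 ± 0.16 (SE), past the threshold adjusted over the list alone (edgeR adjusted p = 0.00728) but not over all genes (0.992), and its trend was 0.23 per µM (0.00299 over the list, 1 over all genes). In the thyroid list the iodide transporter slc5a5 (chromosome 8, 13364950 to 13382352) was at -1.46 ± 0.45 (SE) and the deiodinase dio2 (chromosome 17, 16873417 to 16876753) at 0.71 ± 0.23 (SE), each with an edgeR adjusted p of 0.0398 over the list alone and 0.992 over all genes. Both had low counts, with a mean log2 CPM of -1.45 for slc5a5 and 0.51 for dio2. At 2.8 µM and 5 dpf 4 of the 63 lists held a member that passed over its list alone. About 5% of lists would by chance, so passing in this way is weak evidence for six7, slc5a5 and dio2.

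At 2.8 µM and 5 dpf glutamate signalling genes had a median log2 fold change of 0.19 with 39 of 41 higher (camera adjusted p = 4.11e-06), and cholesterol synthesis genes had -0.26 with 21 of 26 lower (0.000554). Heart muscle genes had -0.24 (0.000974), ribosomal proteins 0.17 (0.00135), hypothalamic neuropeptides 0.17 (0.00187), intestine markers -0.63 (0.0207), hepatocyte markers -0.37 (0.0287) and GABA signalling 0.12 (0.0446). By camera 13 lists passed, 7 higher and 6 lower, and by fry and with an estimated correlation 0 did (adjusted p = 0.918 with an estimated correlation for each list named here). Other splits of these pools passed a median of 16 lists by camera, so 13 is not beyond chance. Without the 3 low-correlation libraries the intestine, hepatocyte and GABA lists had medians of -0.64, -0.38 and 0.1, close to those above, but no longer passed camera (adjusted p = 0.0601, 0.0899 and 0.0601). None of those 3 libraries belongs to the groups compared. None of these 8 lists had a member that passed, adjusted over the list alone or over all genes. The neuron marker level averaged 6.24 ± 0.2 log2 CPM at 2.8 µM and 6.15 ± 0.2 in DMSO (SD, n = 6 each, exact permutation p = 0.422, two-sided).

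Over all genes 0 passed at 2.8 µM at 5 dpf by edgeR (lowest adjusted p = 0.992), with 384 at an unadjusted p under 0.05. DESeq2 and limma-trend gave 0 as well. Limma with sample quality weights called 1 gene, si:dkey-61n16.5 at 1.05 log2. With 3 surrogate variables 3 genes were called, si:dkey-61n16.5 at 1.11, cnga3b (a subunit of the cone ion channel) at 0.71 and six7 at 0.71, and these genes are named here because the count was small, after their values were seen.

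Genes of digestive enzymes, most of them of the exocrine pancreas list, were lower at 5 dpf in the 1.57 µM pools than in DMSO. The bile salt-dependent lipase gene cel.2 (chromosome 21, 11385031 to 11393980, GRCz11) was 113-fold lower, at a log2 fold change of -6.82 ± 1.09 (SE; edgeR adjusted p = 0.00219), and the amylase gene amy2a (chromosome 2, 15612755 to 15626973) was 48.7-fold lower, at -5.6 ± 1.06 (SE; 0.0109). The carboxypeptidase genes cpa5 (chromosome 25, 18459924 to 18470696) and cpa1 (chromosome 25, 18448186 to 18454017) were at -4.94 ± 0.86 and -5.72 ± 0.98, both with an adjusted p of 0.00492; cpa5 stood in the neutrophil list as fixed, not in the pancreas list. The elastase gene ela2 (chromosome 8, 21376290 to 21381735), the lipase gene cel.1 (chromosome 21, 11401247 to 11411366) and the trypsin-like prss59.1 (chromosome 16, 26012569 to 26013852) were at -5.5 ± 1.18, -5.35 ± 0.96 and -5.26 ± 0.99, with adjusted p of 0.0402, 0.00578 and 0.0109. In all, 16 genes passed by edgeR, all of them lower, and 14 of these belong to the 22 tested members of the pancreas list. Adjusted over the list alone, 21 of the 22 did. Counts of close copies such as cel.1 and cel.2, cpa1 and cpa5, and prss59.1 and prss59.2 may share reads and are uncertain one by one.

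The pancreas list had a median log2 fold change of -5.29 at 1.57 µM, -3.03 at 0.88 µM and -1.37 at 2.8 µM at 5 dpf. Camera's adjusted p was 1.61e-30, 1.21e-15 and 0.451, and with an estimated correlation the adjusted p was 0.196, 0.791 and 0.918. Adjusted over the list alone, 21 members were also lower at 0.88 µM and 5 at 2.8 µM (cpa1, zgc:92137, cel.1, cel.2 and pdia2), and 0 passed over all genes at either. Intestine markers had medians of -1.02 at 1.57 µM (camera adjusted p = 2.27e-13; 0.249 with an estimated correlation) and -0.71 at 0.88 µM (1.62e-06; 0.791 with an estimated correlation), with 18 and 7 of 34 lower adjusted over the list alone and 0 over all genes. Hepatocyte markers had -0.75 at 1.57 µM (2.42e-10; 0.551 with an estimated correlation).

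Pools within a group differed widely in these genes. The mean log2 CPM of the pancreas list in DMSO at 5 dpf was 2.73 ± 2.99 (SD, n = 6), from -2.31 in replicate E to 6.46 in replicate B. At 1.57 µM it was -0.82 ± 1.67 (SD, n = 6; exact permutation p = 0.0303, two-sided, adjusted p = 0.749 over 30 such tests), with 6 of 6 pools below the DMSO mean. At 0.88 µM it was 0.59 ± 1.8 and at 2.8 µM 2.5 ± 1.3 (SD, n = 6 each; exact permutation p = 0.175 and 0.872). These means differ from DMSO by -3.55 at 1.57 µM, -2.14 at 0.88 µM and -0.23 at 2.8 µM, less than the edgeR medians above. The edgeR fold changes follow mean counts, on which pools with high counts such as DMSO replicate B weigh most. Replicates C, F and I at 1.57 µM were at -1.88, -2.38 and -2.55, within the range of DMSO pools at 4 dpf (-2.68 to -1.25). The intestine list was also lowest in DMSO in replicate E, at 0.87, and highest in replicate B, at 3.9. At 4 dpf the SD of the pancreas list was 0.56 in DMSO and 0.49 to 1.04 in the PFOS groups (n = 6 each), at low levels. The shared fit assumes that groups vary alike. Its standard errors and p for the pancreas genes at 1.57 µM and 5 dpf may thus be too small.

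**Figure D3:**
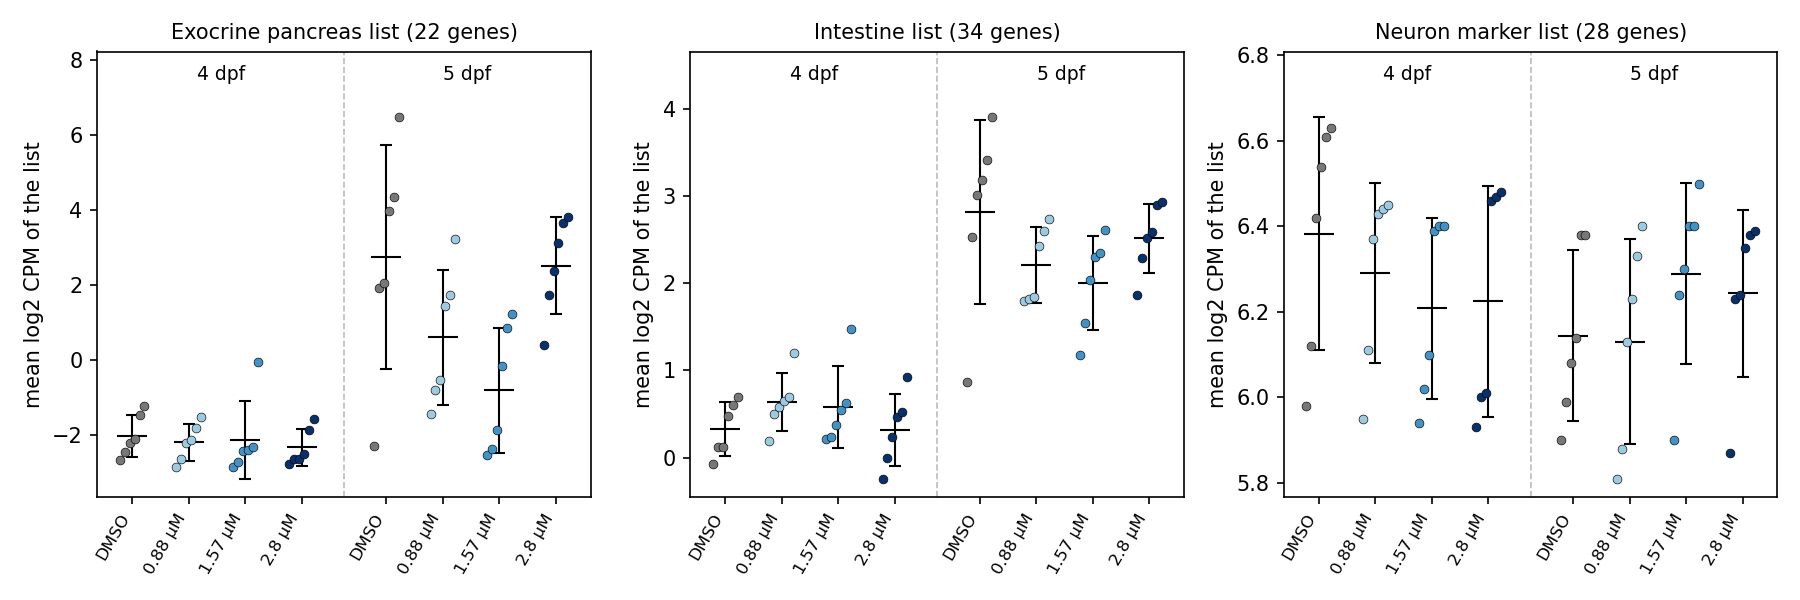
Mean log2 CPM (y axis) of the exocrine pancreas, intestine and neuron marker lists in each pool by PFOS concentration and age, with bars at the group mean and whiskers of 1 SD (n = 6). At 5 dpf the DMSO pools span -2.31 to 6.46 for the pancreas list, and at 4 dpf 10 pools lie at 5.93 to 6.12 and 14 at 6.37 to 6.63 for the neuron list.

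The count of 16 at 1.57 µM rested on few pools. Leaving out 1 pool gave 1 gene, cel.2, without DMSO replicate B, where its log2 fold change went from -6.82 to -5.31 (edgeR adjusted p = 0.0494), 40 without DMSO replicate E, 4 (cel.1, cel.2, cpa1 and cpa5) without 1.57 µM replicate C, F or I, with folds about as large (cel.2 at -6.72, -6.68 and -6.47), and 10 without 1.57 µM replicate D. The count was 0 in 4 other settings, among them a fit of only these 2 groups, limma-trend and sample quality weights, 17 by DESeq2 (12 of them among the 16), 23 with 3 surrogate variables and 11 without the 3 low-correlation libraries. At 0.88 µM and 5 dpf 0 genes passed by edgeR, with 1038 at an unadjusted p under 0.05 and 0 by DESeq2, limma-trend, quality weights and surrogate variables. Without DMSO replicate E 10 did, and without 0.88 µM replicate D the 4 genes cel.1, cel.2, cpa1 and cpb1 did.

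At 4 dpf the lower concentrations changed no gene past the threshold. By edgeR 0 genes passed at 1.57 µM and at 0.88 µM, with 390 and 392 at an unadjusted p under 0.05, and the count was 0 by DESeq2, limma-trend, quality weights and surrogate variables. Glutamate signalling genes at 1.57 µM had a median log2 fold change of -0.2 with 40 of 41 lower (camera adjusted p = 5.81e-09; 0.533 with an estimated correlation), and cartilage markers had 0.24 (4.62e-06; 0.533 with an estimated correlation). No member of either list passed adjusted over the list alone. The neuron marker level at 1.57 µM was also lower, at 6.21 ± 0.21 log2 CPM against 6.38 ± 0.27 in DMSO (SD, n = 6 each, exact permutation p = 0.238, two-sided).

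Trends over the 4 concentrations gave 0 genes by edgeR at both ages, with 1221 genes at 4 dpf and 374 at 5 dpf at an unadjusted p under 0.05, and 0 by DESeq2 and limma-trend. With 3 surrogate variables the count was 0 at 4 dpf and 4 at 5 dpf (si:dkey-61n16.5, cnga3b, esrrgb and six7), and with quality weights it was 857 at 4 dpf and 2 at 5 dpf (si:dkey-61n16.5 and six7). Adjusted over the list alone, ccng1 at 0.27 per µM (adjusted p = 0.0349), the rod phosphodiesterase gene pde6ga at 0.57 (0.0467) and irbpl at -0.26 (0.0469) passed at 4 dpf, each at 0.777 over all genes. At 5 dpf slc5a5 at -0.53 and dio2 at 0.25 per µM passed over the list (0.0287 each), as did 4 pancreas genes, cpa1 at -0.83, zgc:92137 at -0.87, cel.1 at -0.8 and cel.2 at -0.82 (0.0403 each), all at 1 over all genes. For the trends 3 of the 63 lists at 4 dpf and 4 at 5 dpf held such a member, where about 5% would by chance. Between 2.8 and 0.88 µM 0 genes passed by edgeR at both ages, with 550 genes at 4 dpf and 341 at 5 dpf at an unadjusted p under 0.05. The other tools gave 0, except that surrogate variables and quality weights each called si:dkey-61n16.5 at 5 dpf.

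Fold changes at different concentrations share their DMSO pools, which alone makes them correlate. Unchanged groups were simulated by shuffling the deviations from group means of all pools of an age over its groups, DMSO included. They thus do not keep the spread of the real DMSO pools. Across 20021 genes, which are not independent replicates, Pearson's r between 0.88 and 1.57 µM was 0.49 at 4 dpf, where the simulated median was 0.53. At 5 dpf r was 0.71, and the simulated median was 0.55. With the DMSO pools split between the concentrations r was 0.04 and 0.31. The covariance was 0.0317 against a simulated 0.0399 at 4 dpf, and 0.0797 against 0.042 at 5 dpf, where simulated values reached 0.175. Between 1.57 and 2.8 µM r was 0.55 at 4 dpf and 0.63 at 5 dpf (simulated 0.51 and 0.5; split pools 0.13 and 0.16; covariance 0.0426 against 0.0406 and 0.0529 against 0.0405). Between 0.88 and 2.8 µM r was 0.56 and 0.66 (simulated 0.56 and 0.54; split pools 0.15 and 0.19; covariance 0.0444 against 0.0418 and 0.0587 against 0.0465).

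The response to 2.8 µM was not shown to differ between 4 and 5 dpf. Glutamate and GABA signalling genes had medians of -0.26 and -0.38 at 4 dpf and 0.19 and 0.12 at 5 dpf. By camera 32 of 63 lists differed between the ages, and with an estimated correlation or by fry 0 did. In a permutation test of the PFOS and DMSO labels within each age, the differences between ages for glutamate and GABA genes, both 0.48, had permutation p = 0.0739 and 0.0899, and the adjusted permutation p was 0.596 for each over the 63 lists. Over genes 0 passed the test of the difference by edgeR, with 765 at an unadjusted p under 0.05, 0 by DESeq2, limma-trend and surrogate variables, and 701 with quality weights. Log2 fold changes at the 2 ages had a Pearson's r of 0.09 and a Spearman's rho of 0.07 across 20021 genes. Among 8949 genes with a mean log2 CPM of at least 3 these were 0.18 and 0.14, and r was -0.11 without the 3 low-correlation libraries. For differences in mean log2 CPM, a simpler measure, r was 0.07, and unchanged groups simulated on that measure gave r from -0.53 to 0.42, with 76 of 100 as far from 0.

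Between 4 and 5 dpf in DMSO, genes of the liver, gut and pancreas rose most. Age cannot be told apart here from the collection day or anything else that differed between the collections. Of 47 hepatocyte markers 46 rose, with a median log2 fold change of 3.05, among them ahsg1 (6.19 ± 0.53, SE) and tat (4.53 ± 0.51), and 1 fell. Of 22 pancreas genes 21 rose, with a median of 7.51, and of 34 intestine markers 25 rose, with a median of 2.75. The digestive protease and chitinase genes prss59.2 (9.71 ± 1.59; chromosome 16, 26017360 to 26018695, GRCz11), ela2l (9.57 ± 1.47; chromosome 8, 21366771 to 21372486) and chia.1 (8.72 ± 0.91; chromosome 11, 23993298 to 24000172) rose with edgeR adjusted p of 1.32e-05, 4.52e-06 and 1.64e-09, as did amy2a (8.76 ± 1.3; 2.49e-06), ctrb1 (8.23 ± 1.54; 0.000109) and chia.2 (8.04 ± 0.88; 6.3e-09). In DMSO replicate E at 5 dpf the pancreas list stayed at -2.31 log2 CPM, within the 4 dpf DMSO range of -2.68 to -1.25.

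Metabolic genes and some markers of myelinating glia rose over the same day. Of 37 genes of xenobiotic metabolism 24 rose (median 1.85), for example cyp2aa12 (4.06 ± 0.38) and cyp3a65 (4.25 ± 0.48), and of 16 gluconeogenesis genes 12 rose (median 1.59), led by pck1 (5.43 ± 0.68). Of 26 lipoprotein genes 18 rose (median 1.85), and of 21 myelinating glia markers 9 rose and 1 fell (median 0.55), with mpz at 2.09 ± 0.19 and plp1b at 1.91 ± 0.23. Genes that fell included scpp9 (-3.61 ± 0.52; edgeR adjusted p = 1.37e-06; chromosome 1, 43969797 to 43973069), irg1l (-3.03 ± 0.56; 9.64e-05; chromosome 14, 11427052 to 11430611), zdhhc8a (-1.32 ± 0.22; 1.37e-05), rorcb (-1.3 ± 0.37; 0.0126), whose direction was not the same in every setting, mef2ab (-1.24 ± 0.32; 0.0056) and plppr4b (-1.22 ± 0.22; 7.85e-05). The setting that reversed rorcb, the replicate letter as a block, did not give an age effect adjusted for letters. Cell cycle genes had a median of -0.5, and 9 of 32 fell, including plk1 (-0.88 ± 0.16).

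Over all genes 2838 changed between the ages in DMSO by edgeR, 1869 higher and 969 lower, and 39 lists passed camera. The count moved with the setting, to 6027 with 3 surrogate variables and to 7112 with quality weights. It was smaller with the replicate letter as a block, given with the limits, but that setting did not give an age effect adjusted for letters. With an estimated correlation 9 lists passed: hepatocyte (adjusted p = 0.0295 with an estimated correlation), xenobiotic (0.019), intestine (0.0427), lipoprotein (0.0368), gluconeogenesis (0.019), myelinating glia (0.019), inflammation and acute phase (0.0427), ionocyte (0.0427) and corticosteroid response genes (0.019). The pancreas and cell cycle lists had an adjusted p of 0.303 and 0.309 with an estimated correlation. Adjusted over the list alone, 46 hepatocyte, 27 xenobiotic, 27 intestine, 20 lipoprotein, 13 gluconeogenesis, 21 pancreas and 12 myelinating glia genes were higher and 14 cell cycle genes lower.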

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

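In this part the tests of the pancreas and intestine relation, of the order of concentrations, of replicate letters, of sequencing pools, of the neuron list and of its low pools, the fits without 3 libraries and with quality weights, and the reading of the splits for 2.8 µM at 4 dpf were chosen only after the result was seen. Of 158 combinations of a group with a measure, list or gene tested for a library far from the rest, 16 had one. Chance alone gives about 8 on average. The measures are related and some pools stood apart in several of them, so 16 against 8 does not show an excess. No gene by edgeR, and no list by permutation, differed between ages in its response to 2.8 µM.

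Among the 16, replicate A at 1.57 µM and 4 dpf had a pancreas level of -0.07 (others -2.86 to -2.34) and an intestine level of 1.48 (0.22 to 0.63). Replicate A at 2.8 µM and 4 dpf had a median correlation of 0.922 (0.972 to 0.976) and an oxidative phosphorylation level of 6.95 (5.23 to 5.82). Replicate H at 0.88 µM and 5 dpf had a total of 14.5 M counts (20.4 to 23.9 M), 19954 genes detected (22492 to 23689) and a median correlation of 0.915 (0.959 to 0.973). Replicate D at 1.57 µM and 5 dpf had a median correlation of 0.941 (0.968 to 0.977), a ribosomal protein level of 9.17 (7.73 to 8.17), an oxidative phosphorylation level of 6.79 (5.57 to 5.87) and a muscle level of 6.89 (6.18 to 6.44). Replicate C at 2.8 µM and 5 dpf had a neuron level of 5.87 (6.23 to 6.39). Single genes stood apart in DMSO, chia.2 at 2.46 log2 CPM in replicate E at 5 dpf (6.6 to 8.45), zdhhc8a at 2.86 in replicate C at 5 dpf (2.06 to 2.35), mef2ab at 1.8 in replicate G at 4 dpf (2.3 to 2.49) and plppr4b at 2.49 in replicate I at 4 dpf (3.02 to 3.29).

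Exocrine pancreas genes were lower at 1.57 µM at 5 dpf. An effect that grows with dose is argued against, since the pancreas level was 3.32 log2 higher at 2.8 than at 1.57 µM (exact permutation p = 0.00649, for a comparison chosen after the group means were seen and not adjusted), though 4 pancreas genes, cpa1, zgc:92137, cel.1 and cel.2, fell with dose adjusted over the list alone (-0.83, -0.87, -0.8 and -0.82 per µM; adjusted p = 0.0403 each). A candidate explanation is that pools held differing amounts of pancreas and gut tissue: within groups the pancreas and intestine levels had r = 0.68 and rho = 0.53 over 24 libraries (permutation p = 0.00501 and 0.0146, adjusted 0.01 and 0.0255 over 7 relations), but r was 0.36 without the 2 farthest libraries, so the relation rests partly on those, and the pancreas and hepatocyte levels had r = 0.23 and rho = 0.13 (permutation p = 0.385 and 0.584, adjusted 0.479 and 0.584; r = -0.15 without the 2 farthest), which gives no support to differing tissue; it had first been read as in favour at r above 0.5, and the requirement that r also hold without those libraries was added after the value was seen, which leaves it open. Of 100 splits of the pools 2, the real one included, called as many genes, with 16 in the real split and 44 in the highest other. This met the bound set beforehand against chance, but chance is not excluded. Of the 100 splits 16 had as many genes at an unadjusted p under 0.05 as the real 1010, and 12 comparisons were made. What set apart the split with 44 was not examined, so this is weak ground. A larger effect at 1.57 than at 2.8 µM and a slower development of the gut stay open as untested.

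At 2.8 µM at 4 dpf 29 gene lists passed camera at its preset correlation, and 0 did with an estimated correlation or by fry. The higher ribosomal protein list may come from replicate A at 2.8 µM, as its median was 0.67 in the full fit and 0.09 in a fit without the 3 low-correlation libraries, of which only that pool belongs to the groups compared, while the lower GABA list had -0.38 and -0.34 in these fits, which argues against that pool as its source. For the number of lists chance cannot be excluded, with 8 of 100 splits calling as many lists as the 29 of the real split and 32 in the highest other; at 5 dpf 66 of 100 did, with 13 lists in the real split and 41 in the highest other. The median of the other splits was 16 lists at each age. A lower share of nervous tissue in the 2.8 µM pools stays open as untested, since markers of some tissues were higher but levels of hepatocyte (0.02), intestine (-0.01) and pancreas (-0.31) markers differed little from DMSO or were lower.

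Neuron marker levels at 4 dpf fell into 10 pools at 5.93 to 6.12 and 14 at 6.37 to 6.63 log2 CPM, and PFOS at 2.8 µM is argued against as the sole cause of that split, since 7 of the 10 low pools lay outside that group, 2 of them in DMSO, and 3 of its 6 pools were high. The other low pools were 3 at 1.57 µM and 2 at 0.88 µM, so PFOS making a low level more likely stays open. The split was cut at the largest gap in the same values, and whether there are 2 classes was not tested. A step shared by pools with the same replicate letter could account for the low and high levels at 4 dpf (permutation p = 0.0176, with letters holding 69% of the variance within groups against 36.5% on average when permuted), while at 5 dpf the letters held 24%, against 38.1% when permuted (p = 0.848), which argues against such a step there. Letters were not balanced between the groups at 4 dpf: 2.8 µM held replicate E and no F, and DMSO held F and no E. The neuron level was 5.93 in E at 2.8 µM and 5.94 in E at 1.57 µM. It was 6.43 in F at 0.88 µM and 6.54 in F in DMSO. Letter and concentration are thus partly confounded at 4 dpf. The sequencing pool stays open: if the 16 numbers that end the sample titles, each carried by 3 libraries, number the places in a pool, their means should vary less than by chance, and the variance was 0.541 of its mean over permutations (low-tail p = 0.0499), but the test was tried on 2 scores, p was 0.068 on component 2 and the lower adjusted p was 0.068, the adjustment having been added after both were seen. It used deviations from group means in all 48 libraries at both ages, so it was not a test of the 4 dpf levels alone. Whether PFOS at 2.8 µM moved the mean level by a smaller amount also stays open, with a difference of -0.16 from DMSO and an exact permutation p = 0.284.

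Genes called with sample quality weights could not be told from chance: for 2.8 µM at 4 dpf 12 of 100 splits called as many as the 248 of the real split, with 3694 in the highest other, for the trend at 4 dpf 10 did (857, highest other 5040) and for the difference between ages 7 did (701, highest other 6376). Splits that call several times the real count may come from a structure of the samples or from the weighting itself, which was not tested; by edgeR the highest other splits of these comparisons gave 0, 0 and 1.

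For age in DMSO only 1 of 100 splits, the real one, called as many genes (2838, highest other 2167). This met the bound set beforehand against chance, and 1 of 100 is the smallest share that 100 splits can give. By genes at an unadjusted p under 0.05 the real split had 5392 and the highest other 5570, with 2 of 100 as large. The other comparisons called 0 genes, so all 100 splits were as large. For 2.8 µM at 4 dpf 27 of 100 splits had as many genes at an unadjusted p under 0.05 as the real 1202, with 3536 in the highest other, so that number is not beyond chance. The highest other split gave 0 for 2.8 µM, 1.57 µM and the trend at 4 dpf, and 1 for 0.88 µM at 4 dpf, for 2.8 against 0.88 µM at 5 dpf and for the difference between ages. It gave 3654 for 2.8 against 0.88 µM at 4 dpf, and at 5 dpf 504 for 2.8 µM, 1888 for 0.88 µM and 415 for the trend, where the real count was 0. In these comparisons only 5, 1, 10 and 2 of the other splits called any gene. Such large counts may come from a structure of the samples, which was not identified or tested.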

How the results depend on the processing

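The alternatives without 3 low-correlation libraries, with 3 surrogate variables and with sample quality weights were chosen only after the results were seen. The cause of each change below was not tested, except where fewer samples were fitted. In thinned counts with 200 changed genes 50.7% of those changed 2-fold and 16.4% of those changed 1.5-fold were recovered, so many changes under 2-fold would be missed. What sets this limit, and recovery with fewer changed genes, were not tested.

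For 1.57 µM at 5 dpf the 16 genes became 0 when only those groups were fitted, 0 by limma-trend on quantile normalized values and 0 with quality weights. Quality weights gave 248 genes for 2.8 µM at 4 dpf, 857 for the trend at 4 dpf, 1 for 2.8 µM at 5 dpf, 2 for the trend at 5 dpf, 1 for 2.8 against 0.88 µM at 5 dpf, 701 for the difference between ages and 7112 for age. Surrogate variables gave 3 for 2.8 µM, 4 for the trend and 1 for 2.8 against 0.88 µM at 5 dpf, and 6027 for age. Lists at 2.8 µM went from 29 at 4 dpf and 13 at 5 dpf to 0 and 0 with an estimated correlation and to 0 and 0 by fry. Without 3 libraries 27 and 10 lists passed, 21 and 10 of them the same lists in the same direction, and r between ages was -0.11 in place of 0.09; it was 0.18 for genes with a mean log2 CPM of at least 3. Leaving out 1 library gave 1 to 40 genes for 1.57 µM at 5 dpf, 0 to 10 for 0.88 µM at 5 dpf, 2029 to 3084 for age and 0 to 0 for each other comparison. RLE normalization, no filter and the CPM filter changed no count by over 1.5 times and kept all 19 named genes past the threshold.

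Replicate letters, whose meaning the labels do not give, were not taken to pair the samples, since only 9 of 24 same-letter pairs at 4 dpf and 10 of 25 at 5 dpf had a correlation over 0.1. At 4 dpf 9 of 24 libraries correlated best with their own letter, against 2.68 on average with letters permuted within groups (permutation p = 0.0023), a hint from the data that some pools with the same letter share a source of variation; at 5 dpf 4 of 24 did, against 2.66 (0.297). This permutation test was chosen after the data were seen. With the letter as a block the count was 0 for 1.57 µM at 5 dpf and 1800 for age (969 of them among the 2838 in the same direction). No other count of genes moved by over 1.5 times. The block was coded within each age, so with it the contrast of DMSO between ages compares the baseline letter of each age. The 1800 genes, and rorcb, which turned to 0.68, thus do not measure an age effect adjusted for letters. At 2.8 µM 15 lists passed at 4 dpf, and 10 at 5 dpf in place of 13. Counts of lists went from 24 to 10 for 1.57 µM, 33 to 15 for the trend and 22 to 12 for 2.8 against 0.88 µM at 4 dpf, from 14 to 7 for 0.88 µM and 7 to 15 for 2.8 against 0.88 µM at 5 dpf, and from 32 to 10 for the difference between ages; the other counts of lists moved by less. With the block 14 of the 19 named genes no longer passed, but for those named for age this rests on the same contrast of baseline letters.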

Other observations

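Some genes of the retina, clock and thyroid axis also changed between 4 and 5 dpf in DMSO, by edgeR's quasi-likelihood test. The collection day, which differed with age, could not be separated from it. Of 31 cone genes 4 rose and 3 fell (5 and 5 adjusted over the list alone): the cone transducin gene gnb3a fell (-0.97 ± 0.17 log2, SE; adjusted p = 2.84e-05), while the red and green cone opsins opn1lw1 and opn1mw2 rose by 1.98 ± 0.41 and 1.4 ± 0.31 (adjusted p = 0.000436 and 0.00109). Of 27 bipolar, amacrine and ganglion cell markers 10 fell, among them grm6b (-1.02 ± 0.2) and isl1 (-0.73 ± 0.14). Of 36 clock genes 4 rose and 7 fell (6 and 8 adjusted over the list alone): the clock activators arntl2 and arntl1a fell (-1.08 ± 0.13 and -0.93 ± 0.16; adjusted p = 4.27e-08 and 1.92e-05), while nfil3-6 rose by 2.11 ± 0.38 (5.43e-05). The deiodinases dio1 and dio3b rose by 2.42 ± 0.32 and 2.32 ± 0.32, and tg, which encodes thyroglobulin, rose by 1.41 ± 0.22 (adjusted p = 3.91e-07, 6.98e-07 and 8.63e-06). The bipolar and thyroid lists passed camera (adjusted p = 8.14e-05 and 0.04), with an adjusted p of 0.16 and 0.112 with an estimated correlation; the cone and clock lists did not pass (camera adjusted p = 0.938 and 0.508). Adjusted over the list alone 12 bipolar genes were lower, and 6 of 19 thyroid genes higher and 1 lower.

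Hepatocyte markers at 0.88 µM and 4 dpf had a median log2 fold change of 0.76 against DMSO, with 45 of 47 higher (camera adjusted p = 1.64e-14; 0.836 with an estimated correlation). Their mean level was 2.56 ± 0.69 log2 CPM there and 1.87 ± 0.78 in DMSO (SD, n = 6 each; exact permutation p = 0.136, two-sided). Neuron and muscle levels moved in opposite directions within groups at 5 dpf, with r = -0.89 and rho = -0.89 over 24 libraries (permutation p = 1e-05 for both, the smallest 100000 permutations can give; adjusted 2.8e-05 over 7 relations), and r = -0.87 without the 2 farthest. At 4 dpf r was -0.47 and rho -0.49 (permutation p = 0.0368 and 0.0259; adjusted 0.0515 and 0.0403), and r = -0.33 without the 2 farthest, so that relation rests partly on those libraries.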
